A study of Mus musculus with 14 samples.

How the data were processed

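Total RNA from mouse duodenum was hybridised to Affymetrix Mouse Gene ST arrays, which read each transcript with many short probes along its length. The 14 arrays came from 9 mice on a mixed background. Per the labels, 3 arrays held duodenum of wildtype mice, 6 held duodenal tumors of mice in which both copies of Lrig1 carry a CreERT2 insertion, and 5 held normal duodenum next to a tumor of the same mouse. The labels place all of these tissues in the proximal duodenum and give the RNA preparation as a column kit with a DNase step. Animals in a group are separate mice, so p-values against wildtype measure the spread between animals. Tumor and adjacent tissue share 5 mice. The p-values between these tissues rest on the difference within a mouse and on a spread per gene estimated from all groups together. Scatter among the wildtype mice therefore enters these p-values and their SEs.

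The deposited table holds 35556 transcript clusters by 14 arrays as log2 signal; the unit was read from the values, which run from 2.87 to 14.8. Affymetrix Expression Console 1.1 and the mm9 genome build are named, per the submitters' processing notes. The background correction, the normalization between arrays and any filter are not given in the sources used here. Array medians lay between 7.11 and 7.29 on the log2 scale, so no further scaling was applied in the fit reported. Values near 14 approach the top of the scale, where large differences between samples can be compressed. The number of arrays limits the precision, and no detection call accompanied the values.

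Gene symbols came from the platform's annotation and were brought up to date through gene identifiers in a table of the GRCm38.p6 assembly, which was used for names only. A single symbol was given to 21789 transcript clusters, several symbols to 1621, and none to 12146. Of those with a single symbol, 21698 were matched by identifier and 91 kept the annotation's own symbol. Clusters with several symbols or none were left out of the gene tests. For the 999 genes with several clusters the one with the highest mean over all arrays was used, which left 19938 genes.

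Differences were tested with limma 3.58.1 in R 4.3.3. All 14 arrays entered a fit of group means, with mouse as a random block (estimated correlation 0.334), and moderated two-sided tests with Benjamini-Hochberg adjustment over all genes at an adjusted p of 0.05. A second threshold asked for a change of at least 2-fold as well. The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The pairing of tumor and adjacent tissue comes from the mouse named in the labels. Deviations from the group means, correlated over genes, averaged r = 0.228 between tumor and adjacent tissue of the same mouse and -0.0563 between different mice. Deviations within a group cancel out, so the second average turns negative by construction when the first is positive. The exact permutation p over all 120 pairings of the 5 mice was 0.00833, one-sided and the smallest these pairings can give. The correlation was positive in 4 pairs and -0.018 in the fifth, that of tumor replicate 5 and adjacent replicate 4. The paired mice also differ in the first letter of their ID, which these pairings do not separate from the mouse.

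The 34 lists of marker and pathway genes held 483 entries, of which 33 had no gene in the table. Each list was tested with limma's camera on the moderated statistics with a preset correlation of 0.01, two-sided and adjusted over the 34 lists. This test compares a list with all other genes. With a correlation estimated from the data no list passed in any comparison, and that p is given beside each call. The fry test, which asks whether a list's genes move on balance one way, was a further alternative. Genes within a list were counted as risen or fallen after adjustment over all genes; a second count, adjusted over the list alone, is given where it differs.

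Named genes are Lrig1, the 10 raised and 10 lowered genes with the largest change in each comparison, and up to 4 members of each list. The first needed an adjusted p below 0.05 and the same direction in all 5 pairs, or non-overlapping groups in comparisons with wildtype. Members of a list were those with the largest change past the threshold, filled up with members that did not pass where fewer than 4 did. Immunoglobulin, T cell receptor, defensin, olfactory, vomeronasal, predicted, small RNA and unnamed genes were left out of the first set.

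The fit was tested on simulated data built from the real means, spread and mouse correlation, over 19938 genes with 100 genes changed per size. In tumor versus adjacent tissue 99% of genes changed by 1 log2 unit were recovered, in tumor versus wildtype 95%, and in adjacent tissue versus wildtype 91%. Calls among unchanged genes numbered 5, 17 and 9. A list raised in the simulation was called in each comparison, with 0 other lists called. The simulated genes varied independently of each other, so this does not test list calls where genes vary together. Every simulated array had the same spread, whereas array weights in the real data ran from 0.248 to 6.78. Planted changes also ease the adjusted threshold compared with data in which few genes change. The recovery therefore does not show how many such changes the real comparison of adjacent tissue with wildtype would find. In the real data the estimated correlation within a list ran from 0.0379 (gut patterning) to 0.913 (pancreatic acinar).

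Alternatives set in advance were a fit without the block, mouse as a fixed effect in the 5 pairs, a fit of the groups compared alone, quantile normalization, leaving out the lowest 30% of genes by mean level, a variance trend with robust estimation, array weights, the mean of a gene's clusters, all clusters, the first letter of the mouse ID as a covariate, and leaving out each array. After the data were seen, settings were added for the arrays with pancreatic transcripts, for those without, and for each ID letter. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.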

Results

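The series compared duodenal tumors of Lrig1-null mice with normal duodenum. Lrig1 encodes a transmembrane protein that restrains ErbB receptor signalling and marks stem cells of the gut, and mice without it develop duodenal adenomas. Expression was measured as log2 array signal in 3 groups. The wildtype group held 3 mice, the tumor group 6 Lrig1-null mice, and the adjacent group normal tissue from 5 of those 6 mice. The first principal component took 55.1% of the variance, the second 13.2%. All 6 tumors lay on one side of the first component, at -51.8 to -35.1. Wildtype replicate 1 lay on the same side, at -16.6, and the other 7 non-tumor arrays lay between 27.4 and 48.7.

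Lrig1 itself (transcript cluster 10546510) was read first, as a check on the labels. Its mean was 9.03 ± 0.71 (SD, n = 3) in wildtype duodenum, 7.20 ± 0.17 (n = 5) in adjacent null tissue and 8.07 ± 0.32 (n = 6) in tumors. Adjacent null tissue lay below wildtype by a log2 fold change of -1.84 ± 0.25 (SE), with no overlap between the groups and an adjusted p of 0.0511 in limma. Over the alternatives that adjusted p ran from 1.39e-05 with array weights to 1.00 without the 4 non-tumor arrays that lack acinar transcripts; it was 0.508 without wildtype replicate 1 and 0.000283 without wildtype replicate 3. Tumors lay above adjacent tissue in 5 of 5 pairs (log2 fold change 0.88 ± 0.17, adjusted p = 0.00102) and below wildtype (-0.96 ± 0.24, adjusted p = 0.0162), where the groups overlapped because wildtype replicate 3 was at 8.22. Whether the probes lie in the part of Lrig1 that the insertion disrupts is not known here, so a remaining signal does not measure remaining protein.

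**Figure D1:**
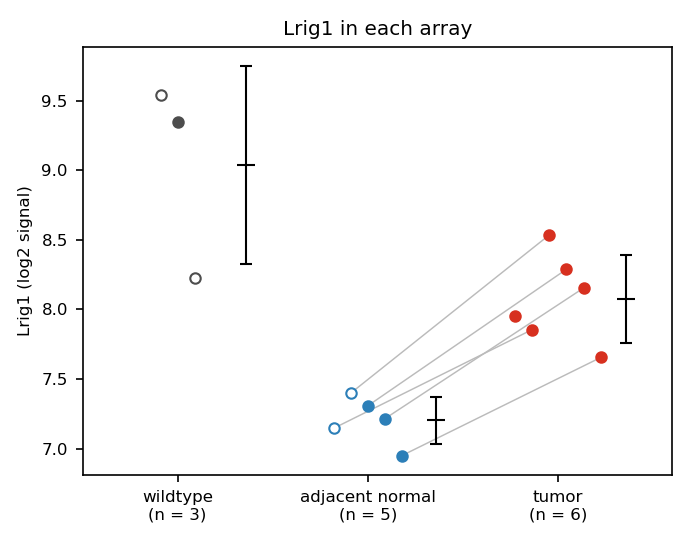
Lrig1 log2 signal in each array by group (3 wildtype, 5 adjacent normal, 6 tumor), with bars for the mean ± SD and grey lines joining tissue of the same mouse; open symbols mark the 4 non-tumor arrays with pancreatic acinar transcripts. Lrig1 was lowest in adjacent null tissue (mean 7.20) and higher in the tumor of each of the 5 matched mice.

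Markers of another organ set some normal samples apart. The mean of 11 pancreatic acinar genes was 13.4 in wildtype replicate 1, 13.0 in wildtype replicate 3, 12.7 in adjacent replicate 1 and 13.7 in adjacent replicate 2. It lay between 7.16 and 7.33 in the other 4 non-tumor arrays and between 7.22 and 9.52 in the tumors. The same 4 arrays carried more S100g, a calcium-binding protein of the proximal duodenum (13.54 ± 0.14 against 8.48 ± 0.64, n = 4 each), and less Enpp7, an intestinal sphingomyelinase (7.74 ± 0.89 against 12.77 ± 0.61). Tumors had S100g at 13.04 ± 0.28 and Enpp7 at 6.53 ± 0.12 (n = 6). These splits were seen in the data and are not groups of the study. Wildtype replicate 1 also had a gastric pit list mean of 12.5, within the tumors' range of 11.5 to 13.2, against 7.15 and 7.87 in the other two wildtype arrays. Its mast cell list mean of 8.02 lay within the tumors' range of 7.75 to 8.61 as well, against 6.28 and 6.11 in the other two.

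**Figure D2:**
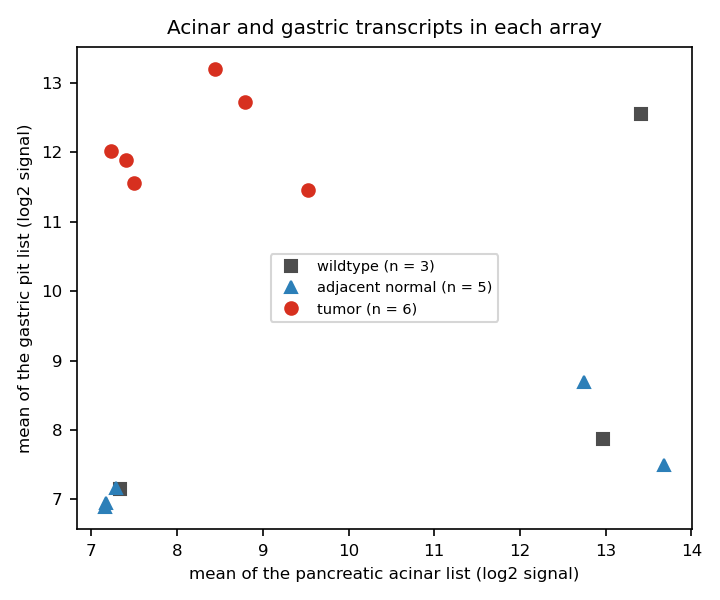
Mean log2 signal of the gastric pit list (13 genes) against that of the pancreatic acinar list (11 genes) in each of the 14 arrays, by group. The 6 tumors lie between 11.5 and 13.2 on the gastric axis, and wildtype replicate 1 is the only non-tumor array in that range.

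The first question was how a tumor differs from the normal duodenum of the same mouse. Tumors carried mucous-cell genes of the stomach at very high levels and digestive genes of the duodenum at lower levels. Gkn2, a gastrokine secreted by surface cells of the stomach, rose from 6.65 ± 1.42 (SD, n = 5) in adjacent tissue to 14.13 ± 0.12 (n = 6), a log2 fold change of 7.49 ± 0.87 (SE; adjusted p = 1.5e-05). Lct, the enzyme that splits milk sugar, fell from 13.03 ± 0.57 to 8.14 ± 0.46, a log2 fold change of -4.86 ± 0.42 (adjusted p = 1.69e-06). Across the 19938 genes, 6313 (31.7%) changed, 3804 upward and 2509 downward. Of these, 658 rose and 613 fell by at least 2-fold. The groups did not overlap for 3424 genes (17.2%, where chance gives 0.433%), and 7227 genes moved the same way in all 5 pairs. Some genes do so by chance, and the latter count was not set against a chance level.

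Apart from predicted genes and the gene families left out, and among genes that moved the same way in all 5 pairs, the largest increases were in Gkn2, Mucl3 (6.80), Vsig1 (6.77), Anxa10 (6.57), Gkn1 (6.41), the gland mucin Muc6 (6.30), Gkn3 (6.27), the chitinase-like Chil4 (5.86), the mast cell protease Mcpt2 (5.85) and the trefoil peptide Tff1 (5.82). The largest decreases were in the brush-border peptidase Naaladl1 (-5.14), the ectoenzyme Bst1 (-5.09), the cytochrome Cyp2b10 (-5.05), Lct, the vitamin B12 and intrinsic factor receptor Cubn (-4.39), the citrate transporter Slc13a2 (-4.33), Enpp7 (-4.32), the cytochrome Cyp3a11 (-4.13), Tmem86b (-4.07) and the antimicrobial lectin Reg3a (-4.06). Adjusted p-values of the 20 genes ranged from 1.36e-07 for Bst1 to 0.0028 for Enpp7. Because the groups share an estimate of spread, wildtype scatter widened some of these SEs. For Gkn1 the SE was 0.71, with an SD of 3.70 in wildtype, 0.36 in adjacent tissue and 0.25 in tumors.

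**Figure D3:**
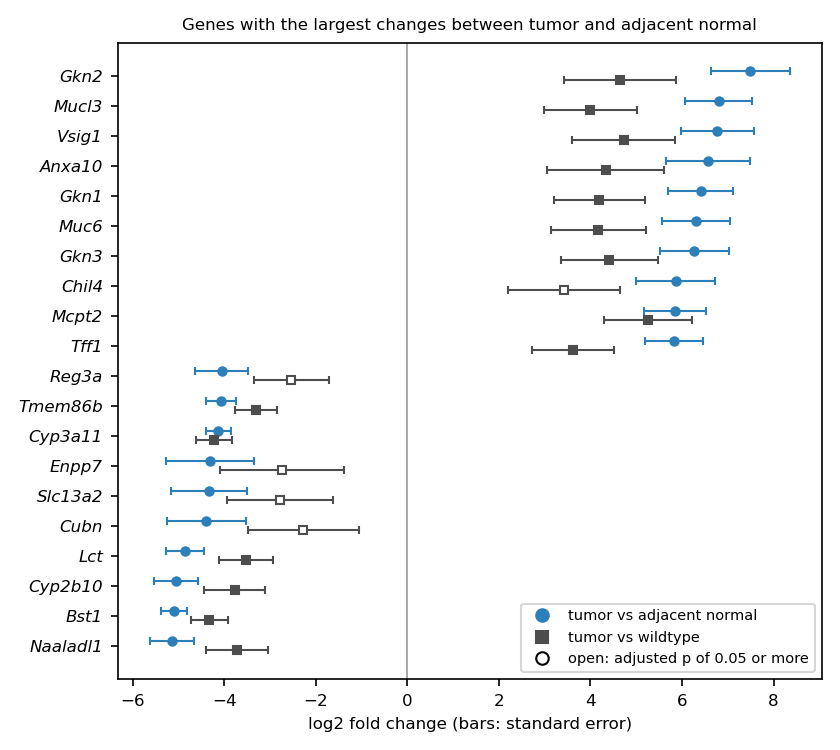
Log2 fold change (bars, SE) of the 10 genes with the largest increase and the 10 with the largest decrease between tumor (n = 6) and adjacent normal tissue (n = 5) among those that moved the same way in all 5 pairs, shown also against wildtype duodenum (n = 3). Chil4, Reg3a, Enpp7, Slc13a2 and Cubn did not pass against wildtype (open symbols).

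Part of these values moved with the split of the normal samples described above. Against the adjacent replicates with acinar transcripts alone, Enpp7 changed by -1.59 ± 0.34 (adjusted p = 0.0135) and Cubn by -2.51 ± 0.52 (adjusted p = 0.0124), whereas Lct changed by -4.26 ± 0.47 (adjusted p = 0.000754). In that setting 19 of the 20 named genes passed and Slc13a2 did not, at -2.67 ± 0.99 (adjusted p = 0.119). Of the genes changed at least 2-fold, 475 of 658 raised and 505 of 613 lowered passed again, and 657 and 613 kept their direction. Within mice whose ID begins with F (3 tumors, 2 adjacent) 1719 genes passed, and within those beginning with B (3 tumors, 3 adjacent) 5696 passed; what the letter stands for is not given in the labels. The 2 adjacent replicates of letter F are the ones with acinar transcripts, so the 2 settings are not separate checks. Within letter F 17 of the 20 named genes passed, and Cubn (adjusted p = 0.0678), Slc13a2 (adjusted p = 0.0804) and Reg3a (adjusted p = 0.0524) did not; within letter B all 20 passed.

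Of the 34 lists, 15 shifted in tumors against adjacent tissue, 8 upward and 7 downward. With an estimated correlation 0 lists passed, while fry called 25, including all 15. Where a single count of risen or fallen genes is given, it was the same when adjusted over the list alone.

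Stomach-type mucous genes rose as a group. In the gastric surface (pit) list 12 of 13 genes rose and 0 fell, with a median log2 fold change of 5.81 (adjusted p = 1.11e-08; adjusted p = 0.328 with an estimated correlation). Gkn2, Vsig1, Anxa10 and Gkn1 led it. The mucin Muc5ac, which covers the surface of the stomach, rose by 3.45 (adjusted p = 0.0265) and was uneven, at 13.93 in tumor replicate 3 and 12.89 in tumor replicate 5 against 7.27 in tumor replicate 1. In the list of Brunner gland and mucous neck cells 6 of 10 genes rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 3.15 (adjusted p = 0.000373; adjusted p = 0.44 with an estimated correlation). Muc6 rose by 6.30 ± 0.74, the pepsinogen Pgc by 5.01 ± 0.59, A4gnt, which caps gland mucin, by 4.75 ± 0.55, and Tff2 by 4.57 (adjusted p = 0.00482). The median of this list was 2.04 against the adjacent replicates with acinar transcripts alone (adjusted p = 0.0156) and 1.98 within mice with ID letter F. The chief and parietal cell list, which holds the hormone gene Gast but not the pepsinogen Pgc, did not shift (median 0.24, 1 of 10 rose and 1 fell, adjusted p = 0.942). The median of the pit list was 4.86 within mice with ID letter F and 5.98 within letter B.

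Genes of absorptive cells fell across 3 lists. In the enterocyte list 18 of 19 genes fell and 0 rose, with a median of -2.42 (adjusted p = 2.94e-34). Its leading members were Lct, the peptidase Dpp4 (-3.71 ± 0.25), the sugar transporter Slc2a2 (-3.53 ± 0.27) and the peptidase Anpep (-3.03 ± 0.19). In the fat absorption list 16 of 17 fell and 0 rose, with a median of -1.36 (adjusted p = 5.59e-19), led by the fatty acid translocase Cd36 (-3.55 ± 0.39), Apoc3 (-3.14 ± 0.18), the fatty acid binding protein Fabp2 (-2.50 ± 0.28) and the cholesterol transporter Npc1l1 (-1.84 ± 0.18). In the list of drug-metabolising and iron-handling genes 12 of 15 fell and 1 rose, with a median of -1.27 (adjusted p = 2.72e-11). The gene that rose was the iron reductase Cybrd1 (3.31 ± 0.93), which was at 12.95 ± 0.70 in the 4 non-tumor arrays with acinar transcripts and 8.09 ± 0.39 in the other 4. For each of the 3 lists the adjusted p was 0.0976 with an estimated correlation.

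Regenerative epithelial genes, which mark fetal gut and injured epithelium, rose in 11 of 12 members with a median of 1.75 (adjusted p = 1.79e-10; adjusted p = 0.0976 with an estimated correlation). Clusterin (Clu) rose by 4.11 ± 0.71, annexin Anxa1 by 3.98 ± 0.36, the interleukin-1 antagonist Il1rn by 3.80 ± 0.33 and Anxa3 by 3.79 ± 0.39. Genes of the crypt stem cell moved both ways: 6 of 13 rose and 5 fell (7 and 5 adjusted over the list alone), with a median of 0.23, while the test against all other genes pointed downward (adjusted p = 0.942). Prom1 (2.46 ± 0.28) and Sox9 (2.27 ± 0.21) rose, while the stem cell receptor Lgr5 (-1.41 ± 0.22) and the water channel Aqp4 (-1.04 ± 0.17) fell. Wnt targets did not shift with camera (median 0.09, adjusted p = 0.493), while fry called them upward (adjusted p = 0.0107). Among 19, Cd44 (2.92 ± 0.23), Ephb3 (1.62 ± 0.17) and Ccnd1 (1.02 ± 0.15) were among the 5 that rose, and Sp5 (-0.74 ± 0.09) among the 3 that fell. In the proliferation list 8 of 21 genes rose and 0 fell, led by Plk1 at 0.54 ± 0.13, with a median of 0.26 (adjusted p = 0.0959).

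The list of ErbB ligands and receptors, the pathway that Lrig1 restrains, rose with a median of 0.55: 8 of 13 genes rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00134; adjusted p = 0.197 with an estimated correlation). Betacellulin (Btc) rose by 2.20 ± 0.13, the receptor Egfr by 1.22 ± 0.14, epiregulin (Ereg) by 1.19 ± 0.24 and Nrg4 by 0.87 ± 0.25. Targets and feedback genes of ERK signalling rose in 12 of 18 and fell in 2, with a median of 0.49 (adjusted p = 0.000219; adjusted p = 0.389 with an estimated correlation). Phlda1 rose by 2.54 ± 0.27, the phosphatase Dusp4 by 1.78 ± 0.17, Fosl1 by 1.54 ± 0.21 and Etv5 by 1.26 ± 0.16. Tumor and adjacent tissue are both Lrig1-null, so these shifts do not measure the loss of Lrig1. Neither list shifted between adjacent tissue and wildtype. There the ErbB median was -0.032 (camera adjusted p = 0.39) and the ERK median 0.039 (camera adjusted p = 0.648).

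Immune genes split. All 13 T and NK cell genes fell, with a median of -1.80 (adjusted p = 3.2e-23), as did 12 of 14 genes of antigen presentation and interferon response, with a median of -1.51 (adjusted p = 6.95e-21). For both the adjusted p was 0.0976 with an estimated correlation. The granzymes Gzmb (-3.17 ± 0.18) and Gzma (-3.05 ± 0.24), the T cell receptor component Cd3g (-2.95 ± 0.27) and Nkg7 (-2.58 ± 0.31) fell most among lymphocyte genes, and the class II genes H2-Ab1 (-2.26 ± 0.16) and H2-Aa (-2.23 ± 0.15), Psmb8 (-2.12 ± 0.18) and the class II regulator Ciita (-1.67 ± 0.17) among the others. Within mice with ID letter F the T and NK cell median was -1.37, within letter B -2.11. Macrophage and dendritic cell genes fell in 8 of 14 and rose in 1 (9 and 1 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.0345; adjusted p = 0.44 with an estimated correlation). This call ended without the block (adjusted p = 0.0501) and within mice with ID letter B (-0.60, adjusted p = 0.211). Csf1r changed by -1.02 ± 0.17, Itgax by -0.84 ± 0.16 and C1qa by -0.74 ± 0.13, while the lipopolysaccharide co-receptor Cd14 rose by 1.46 ± 0.16. The B and plasma cell list had 6 of 10 genes lower and 0 higher, with a median of -0.53 (adjusted p = 0.096).

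Mast cell and inflammatory genes went the other way. Mast cell genes rose in 7 of 10 (8 adjusted over the list alone) with a median of 0.42 (adjusted p = 0.000517; adjusted p = 0.328 with an estimated correlation), and the proteases led by a wide margin: Mcpt2 by 5.85 ± 0.68, Mcpt1 by 4.46 ± 0.72, Mcpt4 by 3.22 ± 0.33 and Cpa3 by 1.77 ± 0.46. Inflammatory cytokine and prostaglandin genes rose in 13 of 19 and fell in 1, with a median of 0.61 (adjusted p = 0.00321; adjusted p = 0.44 with an estimated correlation). Il1a rose by 2.17 ± 0.38, the prostaglandin synthase Ptgs2 by 2.15 ± 0.31, Il1b by 1.60 ± 0.34 and Cxcl2 by 1.60 ± 0.35. The rise was uneven: the list mean was 6.94 in tumor replicate 3 and 7.03 in tumor replicate 5, near adjacent tissue (6.73 to 6.86). In the other tumors it was 7.63 to 7.94. Neutrophil genes had a median of 0.49 with 5 of 10 higher and 0 lower (adjusted p = 0.126). Fibroblast and matrix genes rose in 10 of 20 (12 rose and 1 fell adjusted over the list alone) with a median of 0.59 (adjusted p = 0.019; adjusted p = 0.471 with an estimated correlation), led by the collagenase Mmp13 (2.12 ± 0.43), Timp1 (1.70 ± 0.26), Postn (1.31 ± 0.38) and Mmp3 (1.18 ± 0.24). Against the adjacent replicates with acinar transcripts alone, the fibroblast list had a median of 0.51 (adjusted p = 0.103), and within mice with ID letter F 0.24 (adjusted p = 0.378). The inflammatory list had a median of 0.42 within letter F (adjusted p = 0.184).

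Among secretory lineages of the duodenum, enteroendocrine genes fell in 6 of 18 and rose in 1 (7 and 1 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.00277; adjusted p = 0.419 with an estimated correlation). The hormones Gip (-2.25 ± 0.24), Gcg (-2.18 ± 0.31), Sst (-1.79 ± 0.39) and Cck (-1.35 ± 0.23) led the decrease, and the list median was -0.027 within mice with ID letter F (adjusted p = 0.197) and -0.81 within letter B. The Paneth list had a median of -0.61 with 3 of 8 genes lower, Lyz1 (-2.57 ± 0.60), Defa24 (-2.55 ± 0.53) and Itln1 (-1.47 ± 0.27; list adjusted p = 0.0762). The goblet list had 6 of 11 genes higher and 2 lower, with a median of 0.43 (adjusted p = 0.0613). Pancreatic acinar genes had a median of -1.91 with 0 of 11 passing (adjusted p = 0.162), since 2 of the 5 adjacent samples carried them.

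**Figure D4:**
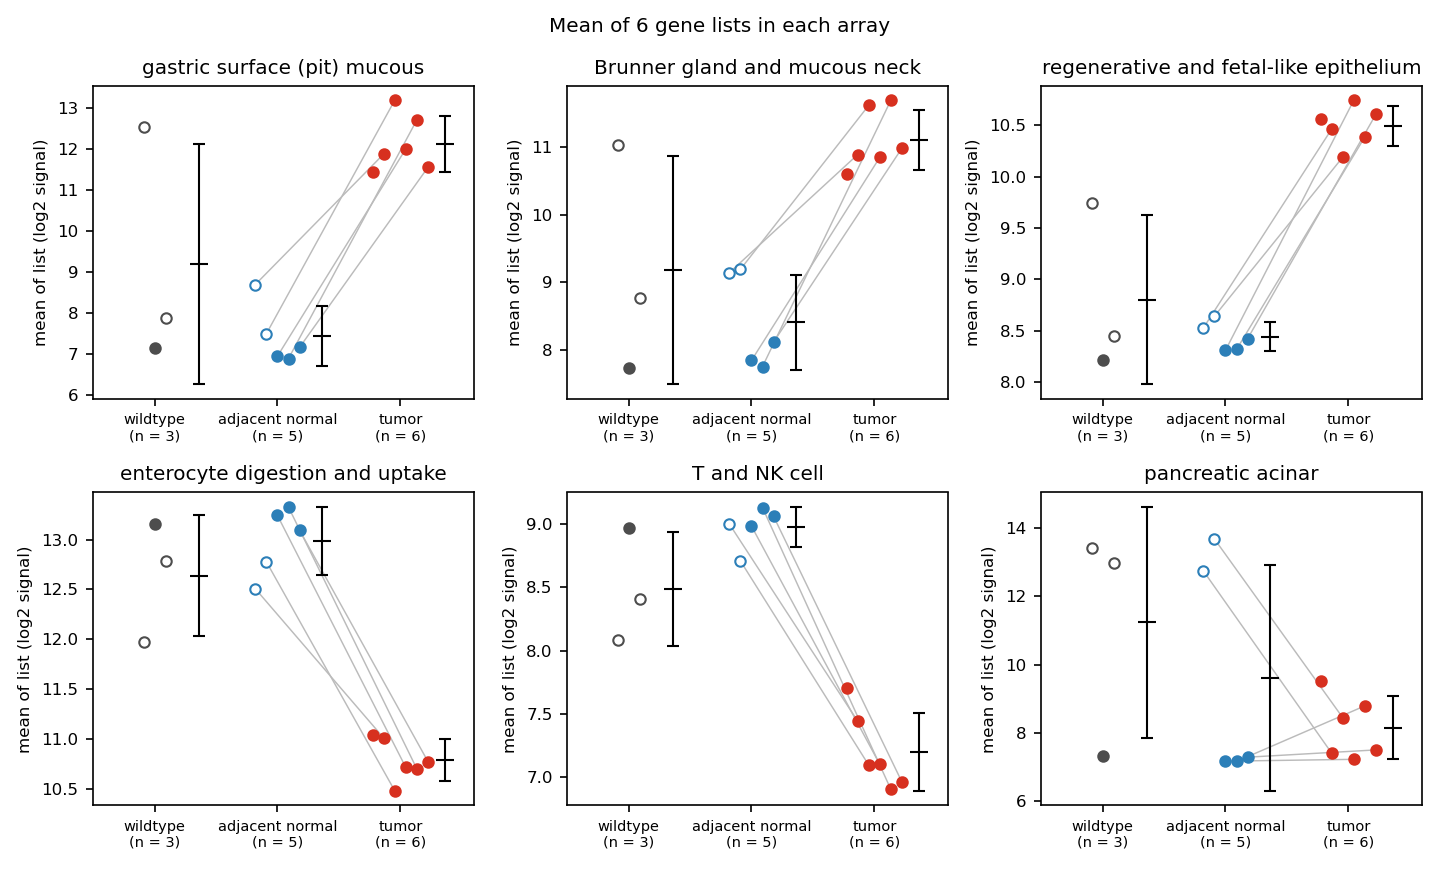
Mean log2 signal of 6 gene lists in each array, by group (3 wildtype, 5 adjacent normal, 6 tumor), with bars for the mean ± SD, grey lines joining tissue of the same mouse, and open symbols for the 4 non-tumor arrays with acinar transcripts. The tumors lie apart from all adjacent samples for the gastric pit, Brunner gland, regenerative, enterocyte and T and NK cell lists, and wildtype replicate 1 lies near the tumors for the gastric pit and Brunner gland lists.

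The second question was how tumors differ from duodenum of mice with intact Lrig1. Mcpt2, a protease of mucosal mast cells, rose by 5.26 ± 0.96 (SE; 6 tumors, 3 wildtype), and the ectoenzyme Bst1 changed by -4.32 ± 0.41. Mcpt2 was at 11.25 in wildtype replicate 1 and at 6.15 and 5.55 in the other two, and without that array it rose by 7.06 ± 0.57; against the wildtype replicates with acinar transcripts alone it did not pass (4.51 ± 1.08, adjusted p = 0.0575). Gastric and regenerative genes were higher and absorptive genes lower. Of 19938 genes 2817 (14.1%) changed, 1924 upward and 893 downward, and 439 rose and 339 fell by at least 2-fold. Groups did not overlap for 2705 genes (13.6%, where chance gives 2.38%). With the same genes left out, and among genes whose groups did not overlap, the largest increases were in Mcpt2, Gkn3 (4.41 ± 1.05), Wfdc18 (4.11 ± 0.76), Lrg1 (4.05 ± 0.53), the complement factor Cfi (3.63 ± 0.56), Chad (3.61 ± 0.68), the keratinocyte envelope protein Sprr1a (3.49 ± 0.69), Clu (3.44 ± 1.00), Mboat1 (3.39 ± 0.70) and Il1rn (3.30 ± 0.46). By the same rule the largest decreases were in Bst1, Cyp3a11 (-4.22), the carbonic anhydrase Car4 (-4.19), Cyp2b10 (-3.76), Naaladl1 (-3.72), Lct (-3.52), the fatty acid transporter Slc27a2 (-3.42), the glycerol channel Aqp7 (-3.37), Tmem86b (-3.30) and the trypsin inhibitor Spink1 (-3.26). Genes with overlapping groups are not in this ranking although some passed with changes as large, among them Vsig1 (4.72), Gkn2 (4.65), Anxa10 (4.33), Gkn1 (4.19), Muc6 (4.17) and the pancreatic ribonuclease Rnase1 (-3.61), which was chosen after its values were seen. For these genes except Rnase1, wildtype replicate 1 lay within the tumors' range, which made the changes smaller. Gkn2 was at 14.20 in that array and at 6.94 and 7.32 in the other wildtype arrays. Single wildtype arrays weighed heavily on the counts: 4526 genes passed without wildtype replicate 1, 940 without replicate 2 and 1090 without replicate 3, and Gkn3, Clu and Mboat1 did not pass without replicate 2 or without replicate 3. Without wildtype replicate 2 and the 3 adjacent replicates that lack acinar transcripts 504 genes passed.

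Against wildtype 16 of the 34 lists shifted, 9 upward and 7 downward; with an estimated correlation 0 passed, and fry called 9, all of them among the 16. The enterocyte list fell in 17 of 19 genes (18 adjusted over the list alone; median -1.95, adjusted p = 4.22e-30), fat absorption in 12 of 17 (13 over the list alone; -1.16, 1.03e-15), drug and iron handling in 8 of 15 (9; -0.92, 2.81e-09), T and NK cells in 10 of 13 (13; -1.32, 6.27e-15) and antigen presentation in 11 of 14 (12; -1.40, 2.03e-20). The regenerative list rose in 8 of 12 (10 adjusted over the list alone; 1.46, 4.56e-09). For all 6 lists the adjusted p was 0.112 with an estimated correlation. Gastric pit genes rose in 8 of 13 (9 adjusted over the list alone) with a median of 3.46 (adjusted p = 0.000203; adjusted p = 0.561 with an estimated correlation), and Brunner gland genes in 5 of 10 with a median of 2.37 (adjusted p = 0.00601; adjusted p = 0.561 with an estimated correlation). Without wildtype replicate 1 the pit median was 5.48 (adjusted p = 6.87e-26). Against the wildtype replicates with acinar transcripts alone the Brunner gland median was 1.61 (adjusted p = 0.0608).

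Signalling, inflammatory, mast cell and fibroblast lists shifted upward against wildtype as well. Among other stromal lists, endothelial (median 0.17, camera adjusted p = 0.473) and smooth muscle genes (-0.39, camera adjusted p = 0.194) did not pass. ErbB ligands and receptors rose in 4 of 13 (6 adjusted over the list alone; median 0.47, adjusted p = 0.0033; adjusted p = 0.206 with an estimated correlation), with Btc at 1.93 ± 0.18 and Egfr at 1.14 ± 0.20; without wildtype replicate 1 the median was 0.72. ERK response genes rose in 7 of 18 (11 rose and 1 fell adjusted over the list alone; 0.45, adjusted p = 0.000133; adjusted p = 0.344 with an estimated correlation). Inflammatory genes rose in 4 of 19 (10 rose and 1 fell adjusted over the list alone; 0.44, adjusted p = 0.00601; adjusted p = 0.561 with an estimated correlation), mast cell genes in 3 of 10 (5 over the list alone; 0.33, 0.00759; adjusted p = 0.561 with an estimated correlation) and fibroblast genes in 6 of 20 (9 over the list alone; 0.65, 0.0078; adjusted p = 0.569 with an estimated correlation). The proliferation list shifted by a median of 0.38 with Mcm5 alone passing (0.55 ± 0.16; 0 of 21 adjusted over the list alone; adjusted p = 0.0078; adjusted p = 0.585 with an estimated correlation). Enteroendocrine genes fell in 2 of 18, Gcg (-1.92 ± 0.43) and Gip (-1.72 ± 0.33), with a median of -0.17 (adjusted p = 0.0206; adjusted p = 0.569 with an estimated correlation). Acinar genes had a median of -3.46 with 0 of 11 passing (list adjusted p = 0.00759; adjusted p = 0.585 with an estimated correlation), and 2 of the 3 wildtype arrays carried these transcripts. Without wildtype replicate 1 the inflammatory (0.38, adjusted p = 0.179), enteroendocrine (-0.20, adjusted p = 0.0836) and acinar lists (-2.32, adjusted p = 0.255) did not pass.

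**Figure D5:**
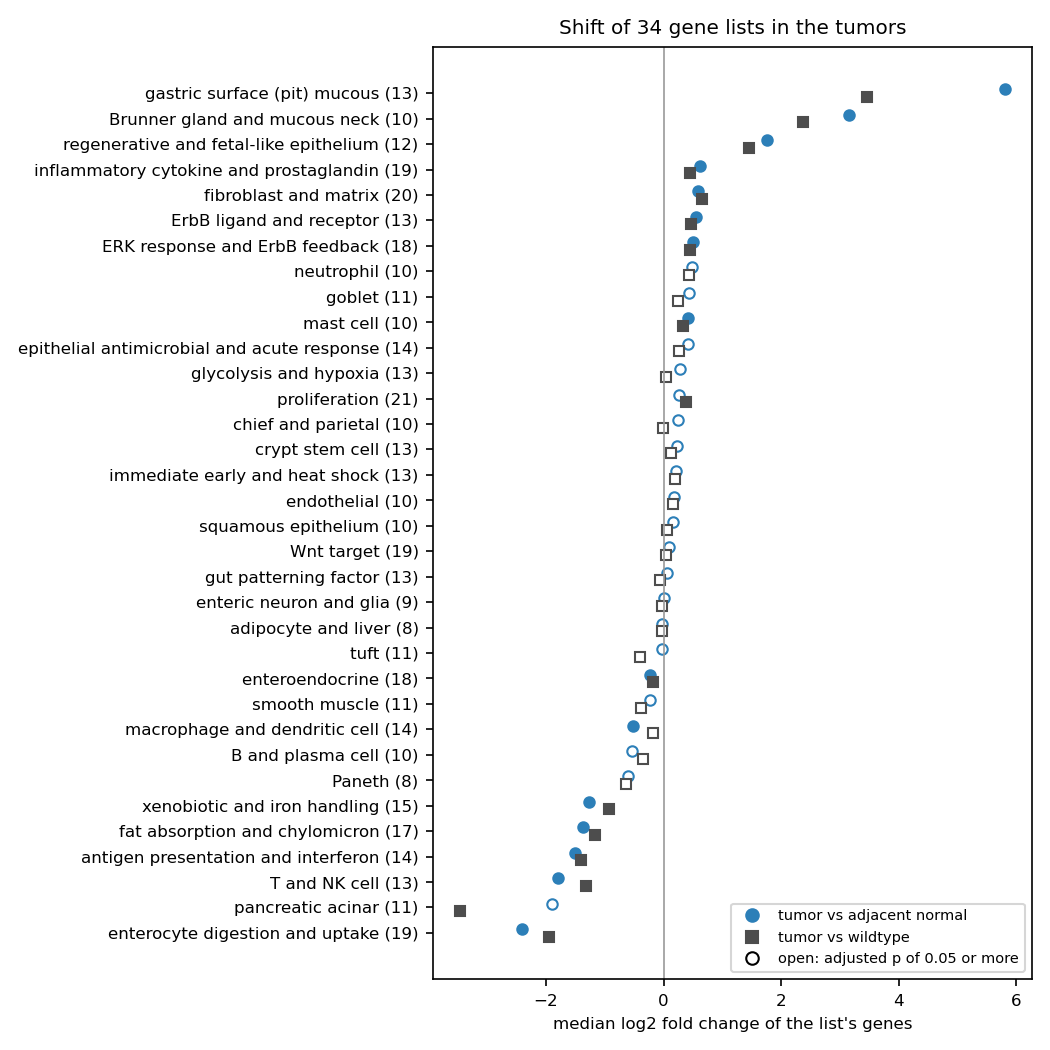
Median log2 fold change of each of the 34 lists in tumors against adjacent normal tissue (circles) and against wildtype duodenum (squares), with the number of genes tested in parentheses; filled symbols passed camera at a preset correlation. The gastric pit list has the largest median against adjacent tissue (5.81) and the enterocyte list the lowest (-2.42).

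Of the 2817 genes that changed against wildtype, 2749 (97.6%) changed in the same direction against adjacent tissue, 1874 upward and 875 downward, and 1 changed in the opposite direction. Independent lists of these sizes would share 367 raised and 112 lowered genes. In 20 simulations with no change but the same shared tumors 0 were shared. Data without changed genes give few calls to share, so these simulations cannot show how much overlap the shared tumors add. With the 6 tumors split so that each comparison had its own 3, the number shared had a median of 1579.5 over 20 splits (range 1072 to 2153), where independent lists would share 228.

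The third question was whether normal tissue of Lrig1-null mice next to a tumor differs from that of wildtype mice. No gene passed in limma: 0 changed, 559 had an unadjusted p below 0.05, and the lowest adjusted p was that of Lrig1. Groups did not overlap for 422 genes (2.12%, where chance gives 3.57%). Quantile normalization, the dim-gene filter and the robust variance trend each called 1 gene, and array weights called 1691. Without wildtype replicate 3, 1 gene passed, Lrig1. The array weights ran from 0.248 for wildtype replicate 1 to 6.78 for wildtype replicate 2. Of the 34 lists 13 shifted at the preset correlation, 6 upward and 7 downward, with 0 genes passing in any list. With an estimated correlation 0 lists passed (lowest adjusted p = 0.576), and fry called 0.

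Several list calls ended without wildtype replicate 1. The gastric pit list had a median of -2.05 (adjusted p = 7.31e-07; adjusted p = 0.646 with an estimated correlation) and -0.09 without that array (adjusted p = 0.846). T and NK cell genes had a median of 0.53 (adjusted p = 1.24e-10; adjusted p = 0.576 with an estimated correlation) and 0.39 without it (adjusted p = 0.0699). Enterocyte (0.33), fat absorption (0.26), drug and iron handling (0.29), macrophage (0.26) and antigen presentation genes (0.11) were the other lists shifted upward, and Brunner gland (-0.79), chief and parietal (-0.23), tuft (-0.34), regenerative (-0.30), mast cell (-0.32) and acinar genes (-1.69) the others shifted downward. With an estimated correlation their adjusted p was 0.646 to 0.803. Without wildtype replicate 1 only the macrophage and dendritic cell list passed, at 0.25 (adjusted p = 0.00692).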

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

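The tests of a wrong label and of a share of tumor RNA serving all genes in wildtype replicate 1, both tests of lower T and NK cell genes, and the islet genes without single arrays were chosen after the results were seen, as was every setting defined by acinar transcripts.

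Acinar enzyme genes were high in 4 of the 8 non-tumor arrays. Acinar genes outside the list were higher there too, by a median of 5.07 over 7 genes (Ctrl at 14.06 ± 0.33 against 7.50 ± 0.10, n = 4 each), which argues against a few genes switched on in duodenal cells. Islet genes were higher by a median of 1.52 over 4 genes, but by 0.743 without adjacent replicate 2, and single arrays gave 4.19 in adjacent replicate 2, 1.84 in wildtype replicate 3, 0.236 in adjacent replicate 1 and -0.0919 in wildtype replicate 1, so they leave pancreatic tissue carried along with the duodenum undecided. Genes of the proximal duodenum were higher by a median of 1.89 over 4 genes, from 0.03 for Slc46a1 to 5.06 for S100g, so the 4 samples may also lie nearer the stomach than the other 4, although the labels call all of them proximal. Both explanations remain open and do not exclude each other, and the 4 arrays come from both genotypes.

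Gastric genes were high in wildtype replicate 1, with Gkn2 at 14.20 against 6.94 and 7.32 in the other two wildtype arrays, and so were genes raised in tumors that are not gastric: Mcpt1 at 11.21 against a mean of 5.53, Mcpt2 at 11.25 against 5.85 and Clu at 11.51 against 8.39. Lrig1 there was 9.54, above the highest tumor by 1.00 (tumor SD 0.32), which argues against a null tumor under a wrong label. Tumor RNA in the sample remains open, although Lrig1 above all other arrays is a value such a mixture would tend to lower. Lowered genes picked after their values were seen differed. Cyp3a11 was at 12.51 (other wildtype mean 12.83, tumor mean 8.50), Car4 at 13.10 (12.28 and 8.37) and Lct at 9.66 (12.67 and 8.14). Against tumor replicate 3 the gastric pit genes would need a median tumor share of 71.2%. The genes lowered 2-fold would need 57.8% (quartiles 32.2% and 80.3%), a difference of 0.134 as fractions, and other raised genes 43.4%. Against the other 5 tumors the difference between pit and lowered genes was 0.369 to 0.692. Pit shares there were 94.6% for replicate 5 and 104% to 128%, more than a mixture can hold, for the other 4. Tumor replicate 3, the closest, was unusual, with Gast at 13.22 against 6.94 to 7.69 in the other tumors. It also had the highest Sox2 of the tumors (8.21). A share taken from that tumor therefore cannot tell tumor RNA from stomach tissue. Genes of the gastric antrum decided neither tumor RNA nor stomach tissue in the sample. Their median was 0.199 against the tumor mean over 6 genes and 0.191 against the other wildtype arrays over 4, with members on both sides of 0. Cckbr could not decide, with group means of 5.98 in wildtype, 5.97 in adjacent tissue and 5.97 in tumors. Barx1 differed little as well (7.95, 7.69 and 7.82). Cym was highest in adjacent tissue (9.87, against 9.14 in wildtype and 9.35 in tumors). With such members the median over the 4 genes could not decide. Gast (higher than in the other wildtype arrays by 3.03) and Sox2 (higher by 2.12) were left out of the 4 because their values had been seen. Both are among the 6, so the median over the 6 includes values already seen. Tumor replicate 3 also raised the tumor means of both. Muc5ac was at 12.88, against 6.78 in the other wildtype arrays and 9.89 ± 2.84 (SD) in tumors. No biological explanation was tested.

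T and NK cell genes were lower in tumors, with a median of -1.80. The 44 genes of the endothelial, fibroblast and macrophage lists had a median of 0.16, which lies above it by 1.96 and argues against a smaller share of all non-epithelial cells. Single lists of this pool differed: fibroblast 0.59, endothelial 0.18 and macrophage -0.52. Outside the pool, the B and plasma cell list had -0.53, mast cells 0.42 and neutrophils 0.49. The test therefore leaves open a smaller share of several immune cell types. Against the adjacent replicates with acinar transcripts alone the T and NK cell median was -1.43, with 13 of 13 genes lower and 12 passing, which argues against position along the gut as the whole cause. Lymphocytes were not counted here, so fewer such cells in tumors and lower transcription per cell both stay untested.

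Other groupings of the arrays were compared with the real one. For tumor versus adjacent tissue 1 of 100 splits drawn gave as many genes, the real one (6313, the highest other 4645), which argues against chance. Of the 32 splits that part all 5 pairs 1 did, again the real one. The highest other, 5346, came from swapping all 5 pairs and leaving the unpaired tumor with the adjacent tissue. A count has no direction, so this swap nearly repeats the real contrast, and the 32 splits decide less than their number. For tumor versus wildtype 2 of 84 splits gave as many genes as the real one, itself included. The other one gave 5036 genes against 2817 and put wildtype replicate 1 in place of tumor replicate 6. Why it called more genes was not tested. Few splits reached the real count, which argues against chance but does not exclude it. For adjacent tissue versus wildtype the real count of 0 is reached by all 56 splits by construction, which says nothing about chance. The highest other, 413, came from setting the 5 non-tumor arrays of mice with ID letter B against the 3 of letter F, which points to a structure of the samples. All 3 of letter F and 1 of the 5 of letter B carry acinar transcripts, so the 413 genes could follow the letter or that split; with the letter, or the acinar score, as a covariate 0 genes passed between adjacent tissue and wildtype.

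Of 342 sets of values tested, 22 (6.43%) had a sample far from the others by Dixon's ratio of gap to range, where chance gives about 1 in 20. Adjacent replicate 1 held 8 of them. It was high for Gkn3 (ratio 0.891, 9.66 against 6.71 to 7.03), Il1a (0.917), Cd14 (0.783) and Mcpt1 (0.72, 8.63 against 6.27 to 6.93), and low for the smooth muscle list (0.719, 9.44 against 10.23 to 10.53), Tmem86b (0.712), Car4 (0.735, 10.08 against 12.29 to 13.09) and Hk2 (0.719). Adjacent replicate 2 was high for Lrg1 (0.938, 9.74 against 7.51 to 7.65) and Cyp2c66 (0.714), adjacent replicate 3 low for Sp5 (0.789) and adjacent replicate 4 high for Cyp3a11 (0.801). Tumor replicate 3 held 6: it was high for the chief and parietal list (0.649, 7.75 against 6.31 to 6.81) and the adipocyte and liver list (0.796), and low for Phlda1 (0.69), Cd79a (0.723), Mzb1 (0.652) and Jchain (0.713, 10.89 against 12.16 to 12.67). Tumor replicate 4 was high for the endothelial list (0.672) and Cdh5 (0.696), and tumor replicate 5 for Car4 (0.701) and Dpp4 (0.654).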

How the results depend on the processing

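Settings based on acinar transcripts or on a single ID letter were chosen after the data were seen. Of the counts and Lrig1 values over all alternatives, 235 stayed near the reported value or on its side of the threshold, 36 moved and 5 newly passed. With a fixed effect of mouse in the 5 pairs, 5575 genes changed between tumor and adjacent tissue, 1316 by at least 2-fold, and 19 lists shifted; without the block 4811 changed, and 2905 between tumor and wildtype. An estimated correlation left 0 shifted lists in each comparison and fry 25, 9 and 0. In adjacent tissue versus wildtype 1 gene passed, by at least 2-fold, with quantile normalization (Lrig1 -1.84, adjusted p = 0.0388), without the lowest 30% of genes (-1.84, 0.0425) and with a robust variance trend (-1.84, 0.0383); the range over all alternatives was 1.39e-05 to 1.00. Array weights gave 9525 genes and 1410 by 2-fold for tumor versus wildtype, and for adjacent tissue versus wildtype 1691, 17 by 2-fold, 0 lists and Lrig1 -2.05. List medians there turned for Brunner gland (0.069), regenerative (0.0327), antigen presentation (-0.21) and acinar genes (0.37). The acinar score as a covariate left 8 lists for adjacent tissue versus wildtype, with acinar genes at 0.0079.

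Without the 4 arrays with acinar transcripts, which leave a single wildtype array assumed to vary like the other groups, 1270 genes changed by 2-fold against wildtype and the acinar median was 0.77. For adjacent tissue versus wildtype 6 lists shifted, and medians turned for Brunner gland (0.0914), immediate early (0.18), regenerative (0.0572), mast cell (-0.0786), antigen presentation (-0.25) and endothelial genes (-0.20). Without the non-tumor arrays that lack acinar transcripts 2181 genes changed against adjacent tissue, 504 against wildtype and 306 by 2-fold against wildtype, and the acinar median of adjacent tissue versus wildtype was 0.0537. Within ID letter F 1719 genes changed against adjacent tissue, 764 by 2-fold. Leaving out single arrays gave 940 to 4526 genes and 412 to 1282 by 2-fold for tumor versus wildtype, and for adjacent tissue versus wildtype 0 to 1 genes, 0 to 1 by 2-fold, 1 to 14 lists (1 without wildtype replicate 1, 8 without adjacent replicate 3 or tumor replicate 6) and Lrig1 at -2.25 to -1.59. Without wildtype replicate 1 the adjacent versus wildtype medians turned for 4 lists, with ranges over single arrays left out of -1.52 to 0.15 for Brunner gland, -0.52 to 0.0455 for regenerative, -0.55 to 0.13 for mast cell and -0.0655 to 0.33 for antigen presentation genes. Fewer arrays enter several of these fits; beyond that the cause was not tested. Without a detection call, low signal cannot be told from background.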

Other observations

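The values per tumor in the last paragraph were chosen after the results were seen, and no other test here was. Several lists that did not shift against adjacent tissue with camera held single genes with large changes. The fry test called the goblet (adjusted p = 0.00149), antimicrobial (0.00459) and glycolysis lists (0.0357) upward, but not the gut patterning list (0.241). The pioneer factor Foxa1 rose by 3.08 ± 0.27 (SE; limma adjusted p = 2.04e-06) and Foxa3 by 1.39 ± 0.25, while Isx, a factor of the intestinal epithelium, fell by 0.88 and Onecut2 rose by 0.66 ± 0.16; 4 of 13 gut patterning genes rose and 4 fell, with a median of 0.06 (adjusted p = 0.935). Goblet cell genes Galnt12 (2.04 ± 0.16), the secretory regulator Spdef (1.97 ± 0.26), Agr2 (1.19 ± 0.14) and Slc12a8 (1.14 ± 0.16) rose. In the antimicrobial list 7 of 14 rose and 2 fell (8 and 3 adjusted over the list alone; median 0.41, adjusted p = 0.211). The hydrogen peroxide generating pair Duoxa2 (3.74 ± 0.53) and Duox2 (3.05 ± 0.45) rose with lactoferrin (Ltf, 2.83 ± 0.26), and Reg3a fell. The glucose transporter Slc2a1 rose by 2.05 ± 0.24 and Pfkfb3 fell by 1.42, among 7 of 13 glycolysis genes that rose and 3 that fell (median 0.28, adjusted p = 0.493).

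Further genes rose in lists that did not shift with camera. The fry test called the neuron and glia (adjusted p = 0.0103), squamous (0.000809), immediate early (0.00665) and neutrophil lists (0.00734) upward. It did not call the tuft, adipocyte and liver, endothelial or smooth muscle lists. Villin-related Avil rose by 2.80 ± 0.32 as the only 1 of 11 tuft cell genes to pass (median -0.029, mean 0.24, adjusted p = 0.932). The receptor Ret rose by 1.88 ± 0.16 and S100b by 1.04 ± 0.11 in the neuron and glia list, where 2 of 9 rose and 1 fell (median 0.01, adjusted p = 0.317). The thyroid hormone carrier Ttr rose by 2.88 ± 0.36, the only 1 of 8 in the adipocyte and liver list (median -0.022, mean 0.30, adjusted p = 0.816). Among squamous genes 4 of 10 rose, led by Krt13 (0.95 ± 0.21), with a median of 0.17 (adjusted p = 0.162). Immediate early genes Egr1 (1.35 ± 0.20), Nr4a1 (1.14 ± 0.19), Hspa1a (1.09 ± 0.34) and Fosb (1.02 ± 0.21) were the 4 of 13 that rose (median 0.21, adjusted p = 0.0959). Endothelial genes Cdh5 (0.55 ± 0.15) and Esam (0.39 ± 0.12) rose among 10 (median 0.18, adjusted p = 0.639), and 0 of 11 smooth muscle genes passed (median -0.23, adjusted p = 0.397). Among neutrophil genes Cxcr2 rose by 0.98 ± 0.30 and S100a8 by 0.70 ± 0.16.

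The tumors differed among themselves in pit-cell mucin. Muc5ac ranged from 7.27 to 13.93 (n = 6), and Psca from 8.46 to 13.82, whereas Muc6 stayed between 13.49 and 14.23. Tumor replicate 3 had the highest Muc5ac and also the highest Gast (13.22) and Sox2 (8.21) among the tumors.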
